A study of Mus musculus with 16 samples.

How the data were processed

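Gene expression was measured in mouse bone marrow-derived macrophages (C57BL/6) on 16 arrays of 1 colour. Macrophage colony-stimulating factor (M-CSF) and the cytokine RANKL turn these macrophages into osteoclasts, the cells that resorb bone. Per the labels, cells received either DW, the control treatment as it is labelled, or 1 mM dimethyl α-ketoglutarate (αKG), an ester of a tricarboxylic acid cycle intermediate. The 2 arrays at 0 h had M-CSF and DW without RANKL. With RANKL, DW arrays were made at 3, 6, 12, 24, 48 and 72 h, and αKG arrays at 0.5, 1, 3, 6, 12, 24, 48 and 72 h, with 1 array per condition and time. The phase named in the labels puts neighbouring times together in 8 groups of 2 arrays: 0 h; DW early (3 and 6 h), intermediate (12 and 24 h) and late (48 and 72 h); the same phases with αKG; and a fast αKG group (0.5 and 1 h). Nothing in the labels says that arrays came from separate cultures or animals, so p-values measure only the spread between these arrays, part of which is time within a phase.

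The values were used as the authors deposited them, on a log2 scale, after labelling of total RNA with biotin through a whole-transcript terminal labelling kit, per the labels' protocols. The base of the logarithm was taken from the range of the values (0.61 to 13.25). Array medians lay between 4.84 and 4.93, so the values had been normalized between arrays. The summarisation, background correction, normalization method, annotation and genome build are not given in the sources used here. Background and saturation could not be set per gene, and the number of arrays limits the precision.

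Of 33793 features, 23521 had 1 gene symbol, 1814 had several and 8458 are unnamed here. Only features with 1 symbol were used as genes. Gene IDs of 23328 features were found in the mouse gene table (GRCm38.p6), and 0 symbols needed an update. For 1082 of the 22180 genes with more than 1 feature, the one with the highest mean over all arrays was kept. Genes in the lowest 30% of mean value (up to 4.34 log2) were left out, and 15526 genes were tested. Closely related genes such as Tmem176a and Tmem176b, the Ly6 genes, Klra2, Slfn4 and Ifitm6 may share probe sequence with relatives, so their values are less certain.

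Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. RANKL phases and the fast αKG group were compared with 0 h in 1 fit of all 8 groups (8 residual degrees of freedom). The αKG effect was fitted on the 12 arrays at the 6 times that both arms hold, with time as a block, either as 1 effect (5 residual degrees of freedom) or as 1 effect per phase (3 residual degrees of freedom), and the difference between the late and early effects was tested as a contrast. Errors given as ± are standard errors on the log2 scale. Pairing by time came from the labels and was checked in the data: deviations from the arm means correlated across genes at r = 0.50 to 0.75 for arrays of the same time, and each array correlated best with its own time.

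The 32 gene lists (681 members, 626 measured) were fixed before the data were examined. They cover osteoclast genes and their regulators, metabolic, stress and cell cycle pathways, inflammatory programmes, and markers of other marrow cell types. Lists were tested with camera (preset correlation 0.01), adjusted over the 32 lists, and again with an estimated correlation and with fry, which asks whether a list's genes move one way on balance. No list called by camera passed with an estimated correlation in any comparison. Counts adjusted over the list alone take the limma p-values of that list's genes only. They are not corrected over the 32 lists or over the comparisons, so they are weaker than calls over all genes. For αKG over the 6 times, list means were tested by an exact two-sided sign-flip test over 64 sign patterns. Its smallest p is 0.03125, so no list can pass adjustment over 32 lists unless most of them reach it together.

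Genes were named by a rule also fixed beforehand: for each comparison the 10 highest and 10 lowest log2 fold changes past the threshold, for the 6 matched times also with 1 sign at all 6; predicted, clone-named, microRNA and small nucleolar RNA genes were skipped. Up to 4 members with the smallest p of a discussed list were added, and a few anchor genes (Acp5, Ctsk, Mmp9, Dcstamp, Calcr, Nfatc1, Irf8, Slc7a11 and Hmox1) in every comparison. Where no gene passed, the 5 highest and 5 lowest moderated statistics were given as values only.

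Alternatives were no filter on dim genes, a filter at the lowest 50%, quantile normalization, centring on array medians, eBayes without a trend or in robust form, fits of only the groups compared, fits without the time block, a line in log2 time, and leaving out each array or pair of arrays in turn. The gene tests for late RANKL, αKG over the 6 times and late αKG were also run on simulated data with 200 changed genes among 15526. For late RANKL arrays, 73% of genes changed by 1 log2 and 95% of those changed by 2 log2 were recovered, with 9 false calls among 177. For αKG over the 6 times, 100% were recovered at both sizes, with 17 false calls among 217, and for late αKG 98% and 100%, with 9 false calls among 207. The simulated change was the same in every changed array and the noise was independent. These shares therefore do not apply to effects that vary between times. The sign-flip test gave p under 0.05 for 3% of simulated lists with no effect, a share that its smallest p of 0.03125 fixes in advance. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots with matplotlib 3.10.9.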

Results

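The series follows mouse bone marrow-derived macrophages as M-CSF and RANKL turn them into osteoclasts, with or without 1 mM dimethyl αKG, and asks how αKG changes osteoclast formation. It holds 16 arrays in 8 groups of 2, and apart from 0 h every condition and time is a single array. The 2 arrays at 0 h differed little (SD of their difference 0.196 log2 over 15526 genes, 9 genes differing at least 2-fold). Arrays separated mainly by time: the first principal component held 34.9% of the variance and the second 23.2%. The DW array at 72 h stood farthest from the others (mean correlation with them 0.929), and both arrays at 12 h had the lowest scores on the second component (-27.6 and -27.9).

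**Figure D1:**
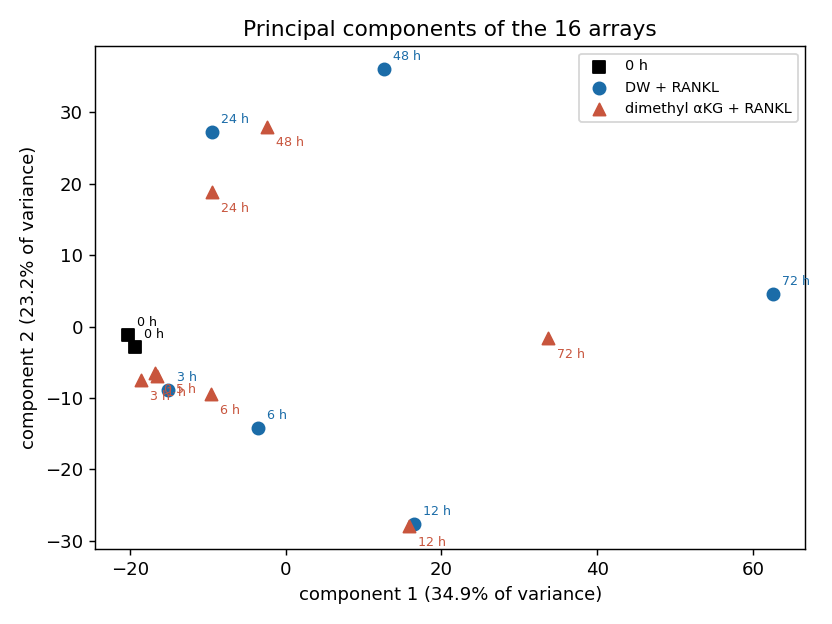
Scores of the 16 arrays on the first 2 principal components of the log2 values, with 1 point per array labelled by hours. Black squares are the 2 arrays at 0 h, blue circles DW with RANKL and red triangles αKG with RANKL. Component 1 held 34.9% and component 2 held 23.2% of the variance.

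The first question was how RANKL changes the macrophages with DW. In late DW arrays (48 and 72 h) the genes of bone resorption rose most. Mmp9, a matrix metalloproteinase, rose by 6.91 ± 0.60 log2 (adjusted p = 0.000193, limma), and Ctsk, the collagen-degrading cathepsin K, by 6.54 ± 0.44. Atp6v0d2, a proton pump subunit, rose by 6.07 ± 0.58, Car2, carbonic anhydrase II, by 6.03 ± 0.56, and Acp5, tartrate-resistant acid phosphatase, by 4.96 ± 0.44. The fusion genes Ocstamp (5.17 ± 0.49) and Dcstamp (4.94 ± 0.47) rose too, as did the receptor gene Oscar (5.37 ± 0.93), the actin-severing Scin (5.40 ± 0.57) and Mmp14 (5.05 ± 0.52). In the other direction F13a1 changed by -4.91 ± 0.54, the monocyte gene Ly6c2 by -4.14 ± 0.56, Ppbp by -3.96 and Chil3 by -3.80. The neutrophil genes Elane (-3.48), Mpo (-3.11), S100a8 (-2.90) and Ngp (-2.75) fell, as did Ccnd2, a cyclin (-3.00), and Stat4 (-2.96).

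By list, 21 of 30 osteoclast genes rose and 1, Trem2 (-0.78), fell in late DW arrays (24 rose and 2 fell adjusted over the list alone). The list's mean change was 2.91 log2, and its adjusted p = 0.117 with an estimated correlation. Of 20 RANK signalling genes and osteoclast transcription factors, 10 rose (11 adjusted over the list alone), among them Prdm1 (2.97 ± 0.33), Fosl2 (2.53 ± 0.28), Nfkb2 (2.11 ± 0.19) and Nfatc1, the master regulator of osteoclast genes (1.73 ± 0.27); adjusted p = 0.0776 with an estimated correlation. Calcr, the calcitonin receptor, stood at 3.20 ± 0.90 and did not pass (adjusted p = 0.0581).

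Some mitochondrial and proton pump genes rose too. Of 34 oxidative phosphorylation genes 15 rose (20 adjusted over the list alone), such as Uqcrc2 (0.89 ± 0.14) and Sdhb (0.92 ± 0.18), with adjusted p = 0.165 with an estimated correlation. Of 25 tricarboxylic acid cycle genes 9 rose (15 adjusted over the list alone), such as the pyruvate dehydrogenase genes Pdhb (1.15 ± 0.17) and Pdha1 (0.80 ± 0.13) and citrate synthase Cs (0.60 ± 0.10); adjusted p = 0.0776 with an estimated correlation. Of 17 V-ATPase genes, which acidify the resorption space, 9 rose, such as Atp6v1b2 (1.09 ± 0.15), and Atp6v0a1 fell (-1.13 ± 0.15), against 12 and 1 adjusted over the list alone; adjusted p = 0.311 with an estimated correlation. Of 22 cell fusion and actin genes 7 rose, led by Src (3.51 ± 0.28), and 2 fell (8 and 3 adjusted over the list alone). The list had adjusted p = 0.42 in camera with an estimated correlation. Its members Src, Dcstamp, Ocstamp, Atp6v0d2 and Itgb3 are in the osteoclast list as well.

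Most neutrophil genes and some macrophage genes fell in late DW arrays. Of 14 neutrophil genes 11 fell (12 adjusted over the list alone), such as Lcn2 (-2.56 ± 0.28), Mmp8 (-2.40 ± 0.23) and Camp (-1.87 ± 0.19); adjusted p = 0.116 with an estimated correlation. Of 22 monocyte and macrophage genes 7 fell (9 adjusted over the list alone), such as Cx3cr1 (-2.26 ± 0.25), the scavenger receptor Cd36 (-1.87 ± 0.13) and Fcgr1 (-1.80 ± 0.23); adjusted p = 0.116 with an estimated correlation. Of 20 NRF2 target genes, which protect against oxidants, 3 fell (4 adjusted over the list alone), Hmox1 (-1.83 ± 0.20), Gclc (-1.28 ± 0.27) and Fth1 (-0.30 ± 0.06); adjusted p = 0.636 with an estimated correlation. For G2/M and mitosis genes 0 of 25 passed, also adjusted over the list alone, with a mean of -0.99 log2; adjusted p = 0.636 with an estimated correlation. Without the 48 h array 25 of them passed, all lower, and without the 72 h array 0.

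In all, 1031 genes changed in late DW arrays, 519 higher and 512 lower (limma, 15526 genes tested); the balance was 581 and 478 with quantile normalization and 439 and 575 with centring on array medians. Without the 48 h array 2179 genes passed, without the 72 h array 459, without either 0 h array 296 or 251, and with only these 2 groups in the fit 115; the count of osteoclast genes that rose was 23 without 48 h and 17 without 72 h. RANKL and time in culture cannot be told apart here, since the arrays without RANKL were all at 0 h.

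In early DW arrays (3 and 6 h), some genes of NF-κB signalling and inflammation rose. The highest of all genes were Acod1, which makes itaconate (4.38 ± 0.66), Mmp14 (3.91 ± 0.52), the lectin receptor Clec4e (3.62 ± 0.60), the chemokine Cxcl10 (3.48 ± 0.57) and Traf1 (3.06 ± 0.41). Birc3 (2.58 ± 0.30), Cd69 (2.56 ± 0.36), Icam1 (2.48 ± 0.35), Nfkb2 (2.43 ± 0.19, adjusted p = 0.00075) and Rrad (2.41 ± 0.30) followed. The 6 genes that fell were Rasgrp3 (-1.45), Slc16a6 (-1.42), Snx24 (-1.28), Rhoh (-1.09), Mef2a (-1.09) and Tbc1d2 (-0.80). Of 23 NF-κB and inflammatory genes 4 rose (10 adjusted over the list alone), with adjusted p = 0.0522 with an estimated correlation. Of 20 RANK signalling genes 2 rose, Nfkb2 and Relb (1.68 ± 0.23), against 8 adjusted over the list alone, also with adjusted p = 0.0522 with an estimated correlation. Of 30 osteoclast genes 1 rose (1 adjusted over the list alone), Mmp14, while Ctsk stood at 0.30 ± 0.44 and Acp5 at 0.07 ± 0.44. The total was 53 genes, 47 higher and 6 lower. It rested on every array: 1 gene passed without either 0 h array and 2 without the 3 h or the 6 h array. With only these 2 groups in the fit 775 genes passed.

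In intermediate DW arrays (12 and 24 h) the membrane genes Tmem176b (4.81 ± 0.84) and Tmem176a (4.38 ± 0.81) rose most, then Ly6i (3.90 ± 0.49), Slamf8 (3.51 ± 0.48), Traf1 (3.47 ± 0.41), Mmp14 (3.35 ± 0.52) and Slamf6 (2.98 ± 0.28). Birc3 (2.60), the dicarboxylate transporter Slc13a3 (2.53) and complement factor B, Cfb (2.42), rose as well. The genes lowered most were Slco2b1 (-2.47 ± 0.38), Ccnd2 (-2.23 ± 0.29), Itga8 (-2.13), Rasgrp3 (-1.93), Cd300e (-1.89), Stat4 (-1.80), Snx24 (-1.80), Tpbgl (-1.60), Padi4 (-1.57) and Cd34 (-1.52), and Hmox1 fell too (-1.26 ± 0.20). Of 23 NF-κB and inflammatory genes 4 rose, such as Icam1 (1.97 ± 0.35), and 0 fell (7 and 2 adjusted over the list alone); adjusted p = 0.676 with an estimated correlation. Of 30 osteoclast genes 1 rose (5 adjusted over the list alone), with Mmp9 at 2.87 ± 0.60 (adjusted p = 0.0573) and Acp5 at 1.52 ± 0.44; the list had adjusted p = 0.841 with an estimated correlation. The total was 121 genes, 70 higher and 51 lower. It was 67 without the 12 h array, 27 without the 24 h array, and 7 or 4 without a 0 h array. With only these 2 groups in the fit 0 genes passed (limma), with 1194 at an unadjusted p under 0.05.

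Against 0 h, 0 genes passed in the fast αKG arrays (0.5 and 1 h with RANKL), with 540 at an unadjusted p under 0.05 (limma). With only these 2 groups in the fit 96 genes passed. The highest moderated statistics belonged to Ptger4 (2.02 ± 0.30), Nfkbiz (2.08 ± 0.31), Cd69 (2.17 ± 0.36), Cxcl1 (1.57 ± 0.28) and Phf13 (0.77 ± 0.14), and the lowest to Zfp628 (-0.76), Zfp90 (-0.73), Nr5a1 (-0.40), Zfp809 (-0.48) and Rhoh (-0.49), none past the threshold. Adjusted over the list alone, 7 of 23 NF-κB and inflammatory genes and 7 of 22 immediate early genes passed, all higher, such as Nfkbia (2.13 ± 0.40) and Junb (1.61 ± 0.33). The lists had adjusted p = 0.115 and adjusted p = 0.129 with an estimated correlation. NRF2 target genes had a mean of 0.01 log2, and Slc7a11 stood at 0.49 ± 0.52. These arrays differ from 0 h in both RANKL and αKG, and DW arrays at 0.5 and 1 h were not analysed here, so the agents cannot be told apart.

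The central question was what αKG changes at matched times. Over the 6 times, several genes of the antioxidant NRF2 programme rose with αKG. Nqo1, a quinone reductase, rose by 1.20 ± 0.18 log2 (adjusted p = 0.0353, limma), Gclm, of glutathione synthesis, by 1.02 ± 0.09 (adjusted p = 0.00428) and Hmox1, heme oxygenase 1, by 0.93 ± 0.10 (adjusted p = 0.0112). Spry3 (1.25 ± 0.14), the chemokine Ccl3 (1.13 ± 0.16), Procr (1.04 ± 0.15), Ptgr1, a reductase of lipid mediators (1.01 ± 0.10), Slpi (0.87), Ptgir (0.80) and Mmp12 (0.79) were the other highest. Cd4 fell by 1.62 ± 0.17 and Mmp14 by 1.58 ± 0.14, and Adgre4 (-1.14), the complement regulator Cd55 (-1.11), Saa3 (-0.95), Mmp9 (-0.80 ± 0.12), Tmem176a (-0.77), Tmem176b (-0.77), Fgl2 (-0.72) and the transferrin receptor Tfrc (-0.71) fell as well. Slc7a11, the cystine transporter, had the larger value of 2.20 ± 0.39 but did not pass (adjusted p = 0.0587): its difference was 2.48 at 3 h, 4.05 at 6 h, 3.07 at 12 h, 2.17 at 24 h, 0.51 at 48 h and 0.95 at 72 h.

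Of 20 NRF2 target genes 8 rose over the 6 times and 0 fell (18 adjusted over the list alone), among them Me1 (0.68 ± 0.08) and Pgd (0.38 ± 0.05), which supply NADPH. The list's mean difference was above 0 at 6 of 6 times: 0.48 at 3 h, 0.97 at 6 h, 0.91 at 12 h, 0.61 at 24 h, 0.47 at 48 h and 0.34 at 72 h. Its mean was 0.63 ± 0.11, with an exact sign-flip p = 0.03125, the smallest the test can give, and 0.167 adjusted over 32 lists; adjusted p = 0.24 with an estimated correlation. The count of 8 was 2 without the 6 h pair, 1 without the 12 h, 24 h or 48 h pair and 12 without the 72 h pair. Of 16 glycolysis genes 1 rose, the glucose transporter Slc2a1 (0.68 ± 0.11), against 4 adjusted over the list alone. The list's mean was above 0 at 6 of 6 times (0.17 ± 0.02, exact p = 0.03125, adjusted 0.167; adjusted p = 0.24 with an estimated correlation). These lists were not alone in reaching the smallest exact sign-flip p. Osteoclast genes (-0.52), oxidative phosphorylation genes (-0.13) and T and NK cell genes (-0.28) reached it too, below 0 at 6 of 6 times. Heat shock genes (0.12) did so above 0 at 6 of 6 times. The T and NK cell list has only 6 tested genes, and Cd4 (-1.62) made up most of its mean, so it does not stand for a cell type.

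In all, 62 genes changed over the 6 times, 41 higher and 21 lower. Of all tested genes 8.3% had 1 sign at all 6 times, against 3.125% by chance. The count fell to 7 without the 6 h pair, 4 without 12 h, 5 without 24 h and 4 without 48 h, and was 174 without 72 h. Without the time block, 20 genes passed in the fit of 8 groups, 20 higher and 0 lower, of which 9 were among the 62, and 0 in a fit of 6 arrays against 6.

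**Figure D2:**
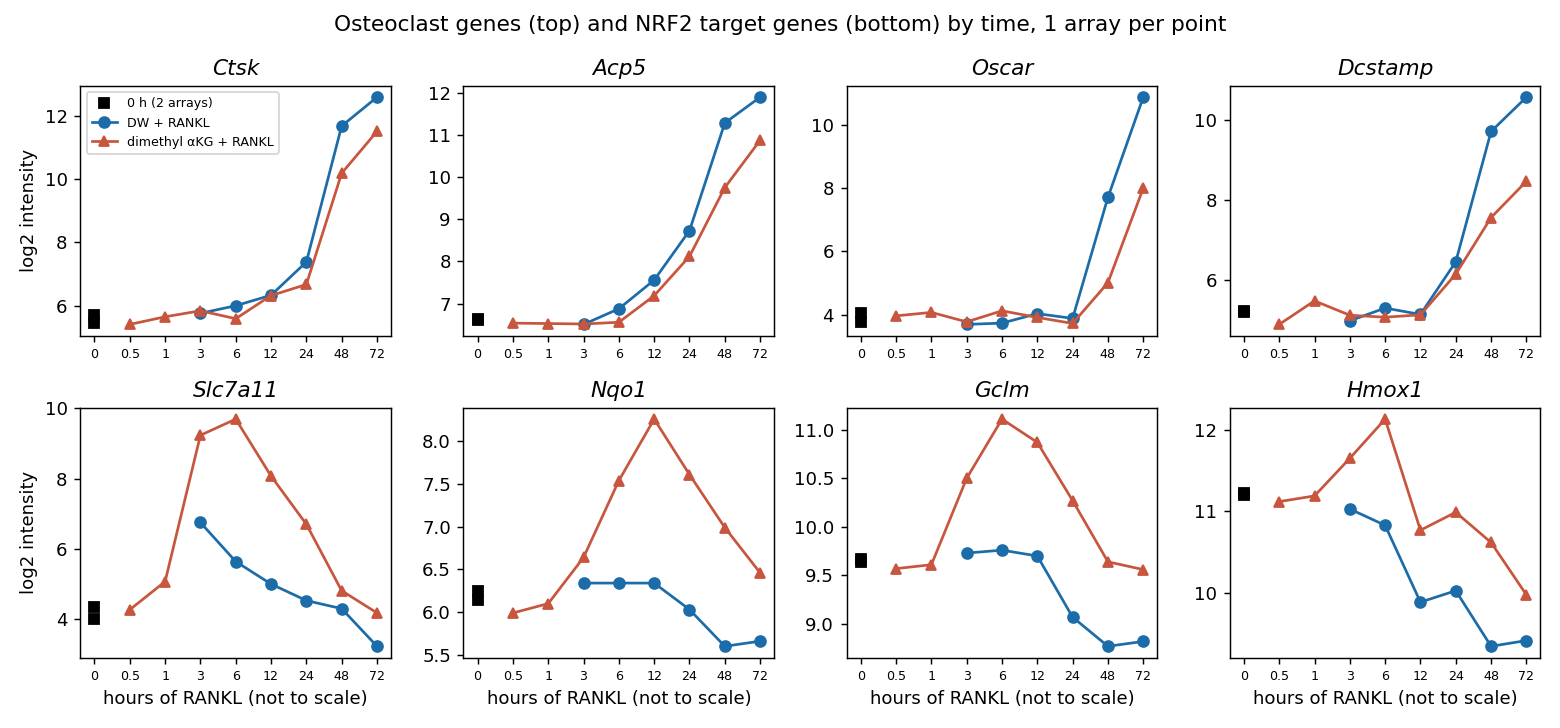
Log2 intensity of 4 osteoclast genes (top) and 4 NRF2 target genes (bottom) by hours of RANKL, not to scale, with 1 array per point. Black squares are 0 h, blue circles DW and red triangles αKG. Ctsk reached 12.58 at 72 h with DW and 11.50 with αKG, and Slc7a11 reached 9.69 at 6 h with αKG against 5.64 with DW.

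In early arrays (3 and 6 h), Slc7a11 rose by 3.26 ± 0.33 log2 with αKG (adjusted p = 0.012), followed by the chemokine Cxcl2 (1.68 ± 0.13), Plk2 (1.67 ± 0.23), the prostaglandin synthase Ptgs2 (1.53 ± 0.16), Procr (1.36), Srxn1, a sulfiredoxin (1.28 ± 0.16), Cpeb2 (1.24), Suco (1.15), Gclm (1.06) and Slc22a4 (0.92). Those lowered were Adgre4 (-1.39 ± 0.20), Mmp14 (-1.14 ± 0.16), Saa3 (-1.13), Tmem176b (-1.10), the kinase Fgr (-1.04), Il21r (-0.94), Tnfrsf14 (-0.78), Acp2 (-0.65), Cxcl16 (-0.57) and Igsf6 (-0.42). Of 20 NRF2 target genes 4 rose (16 adjusted over the list alone), against 1 without the 3 h pair and 0 without the 6 h pair; adjusted p = 0.636 with an estimated correlation. Of 20 ATF4 and amino acid response genes 1 rose, Slc7a11 itself (3 adjusted over the list alone), and Atf3 stood at 0.88 ± 0.17; adjusted p = 0.636 with an estimated correlation. Of 30 osteoclast genes 1 fell, Mmp14 (2 adjusted over the list alone). The total was 25 genes, 15 higher and 10 lower, and it was 2 without the 3 h pair and 0 without the 6 h pair. It was also 0 in the fit without the time block and 5 with the lowest 50% of genes left out.

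In intermediate arrays (12 and 24 h), Slc7a11 (2.62 ± 0.33) and Nqo1 (1.75 ± 0.22) rose most with αKG. The osmolyte transporter Slc6a12 (1.56 ± 0.18), Ptgr1 (1.24), Arrdc4 (1.22), the zinc transporter Slc39a4 (1.20), Gclm (1.19 ± 0.13), the prostaglandin receptor Ptger2 (1.14), the metallothionein Mt2 (1.01) and Gstp1 (0.90) rose too. Mmp14 (-1.64 ± 0.16), Saa3 (-1.18 ± 0.13) and Tfrc (-0.89 ± 0.11) were the 3 that fell. Of 20 NRF2 target genes 3 rose (17 adjusted over the list alone), with adjusted p = 0.408 with an estimated correlation. Of 30 osteoclast genes 1 fell (7 adjusted over the list alone); Mmp9 stood at -0.81 ± 0.13 (adjusted p = 0.0688) and Acp5 at -0.49 ± 0.14, and the list had adjusted p = 0.785 with an estimated correlation. For G2/M and mitosis genes 0 of 25 passed, also adjusted over the list alone, with a mean of -0.57; adjusted p = 0.785 with an estimated correlation. The total was 15 genes, 12 higher and 3 lower, and it was 1 without the 12 h pair and 0 without the 24 h pair. The fit without the time block gave 1.

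In late arrays (48 and 72 h) most osteoclast genes fell with αKG. Oscar changed by -2.79 ± 0.14 log2 (adjusted p = 0.000106), the motor protein gene Myo1d by -2.49 ± 0.22, Akap6 by -2.48 ± 0.33, the integrin Itgb3 by -2.25 ± 0.22 and Cd200 by -2.25 ± 0.31. Dcstamp (-2.14 ± 0.14), F2r (-2.08), Ocstamp (-2.07 ± 0.16), Pip5k1b (-2.07), Car2 (-2.05 ± 0.14) and Calcr (-1.95 ± 0.31) fell too, and by smaller amounts Ctsk (-1.28 ± 0.18), Acp5 (-1.27 ± 0.14), Mmp9 (-1.18 ± 0.13) and Nfatc1 (-0.85 ± 0.09). Fxyd2 (1.84 ± 0.24), Ifitm6 (1.72 ± 0.26), Slc6a12 (1.67 ± 0.18), Klra2 (1.64 ± 0.14), Slfn4 (1.54), Cd36 (1.54 ± 0.10), Ceacam1 (1.49), Spry3 (1.46), the chemokine Ccl6 (1.45) and Rasgrp3 (1.40) rose most. Irf8, a repressor of osteoclast genes, stood at 0.50 ± 0.24 (adjusted p = 0.306).

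By list, 23 of 30 osteoclast genes fell and 1 rose in late arrays (26 and 2 adjusted over the list alone); adjusted p = 0.204 with an estimated correlation. The list's mean difference was -0.10 at 3 h, -0.10 at 6 h, -0.09 at 12 h, -0.36 at 24 h, -1.07 at 48 h and -1.39 at 72 h. Without the 48 h pair 26 fell and without the 72 h pair 20, but in the fit without the time block 0 passed at the same mean of -1.23. Of 20 RANK signalling genes and osteoclast transcription factors 5 fell (7 adjusted over the list alone), such as Fosl2 (-1.33 ± 0.16) and Ppargc1b, a regulator of mitochondrial genes (-1.23 ± 0.14); adjusted p = 0.307 with an estimated correlation. Of 22 cell fusion and actin genes 9 fell and 2 rose (9 and 3 adjusted over the list alone). The list had adjusted p = 0.204 in camera with an estimated correlation. Its members Dcstamp (-2.14), Ocstamp (-2.07), Atp6v0d2 (-1.49), Itgb3 (-2.25) and Src (-1.48) are in the osteoclast list as well. The fall of this list is therefore largely that of osteoclast genes counted again.

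Some mitochondrial and proton pump genes fell with αKG in late arrays. Of 25 tricarboxylic acid cycle genes 10 fell and 0 rose (19 and 1 adjusted over the list alone), such as Idh3a (-0.78 ± 0.13) and Pdha1 (-0.74 ± 0.10); adjusted p = 0.307 with an estimated correlation. Of 34 oxidative phosphorylation genes 9 fell (20 adjusted over the list alone), such as Ndufv1 (-0.60 ± 0.11) and Atp5a1 (-0.43 ± 0.07); adjusted p = 0.416 with an estimated correlation. Of 17 V-ATPase genes 9 fell (13 adjusted over the list alone), such as Atp6v1d (-0.86 ± 0.09); adjusted p = 0.204 with an estimated correlation. These counts leaned on the 72 h pair: without it 2, 1 and 5 genes fell, and without the 48 h pair 17, 20 and 11.

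Some macrophage, interferon-stimulated and NRF2 target genes were higher with αKG than with DW in late arrays. Of 22 monocyte and macrophage genes 6 rose (12 adjusted over the list alone), such as Cx3cr1 (1.13 ± 0.14), Msr1 (0.68 ± 0.09) and Mpeg1 (0.50 ± 0.07); adjusted p = 0.204 with an estimated correlation. Of 23 interferon-stimulated genes 4 rose (19 adjusted over the list alone), Mx1 (0.88 ± 0.18), Oasl2 (0.87 ± 0.18), Zbp1 (0.64 ± 0.14) and Irf7 (0.57 ± 0.11), against 12 without the 48 h pair and 2 without the 72 h pair; adjusted p = 0.416 with an estimated correlation. Of 20 NRF2 target genes 7 rose (8 adjusted over the list alone), such as Nqo1 (1.10 ± 0.22) and Hmox1 (0.92 ± 0.18). The list had adjusted p = 0.505 in camera with an estimated correlation. Hmox1 (-1.83) and Cx3cr1 had fallen by more than these differences in late DW arrays against 0 h. With αKG these genes thus fell less, and stayed below 0 h. Of 25 G2/M and mitosis genes 0 passed (24 adjusted over the list alone), with Ccna2 at 1.01 ± 0.29; adjusted p = 0.544 with an estimated correlation. That list's mean difference was 0.03 at 48 h and 1.52 at 72 h, and 25 genes passed without the 48 h pair and 0 without the 72 h pair.

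In all, 663 genes changed with αKG in late arrays, 325 higher and 338 lower, of which 42 and 87 by at least 2-fold. The count was 1882 without the 48 h pair and 326 without the 72 h pair. It was 323 with eBayes without a trend and 7 in the fit without the time block, where the change within a phase counts as spread.

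**Figure D3:**
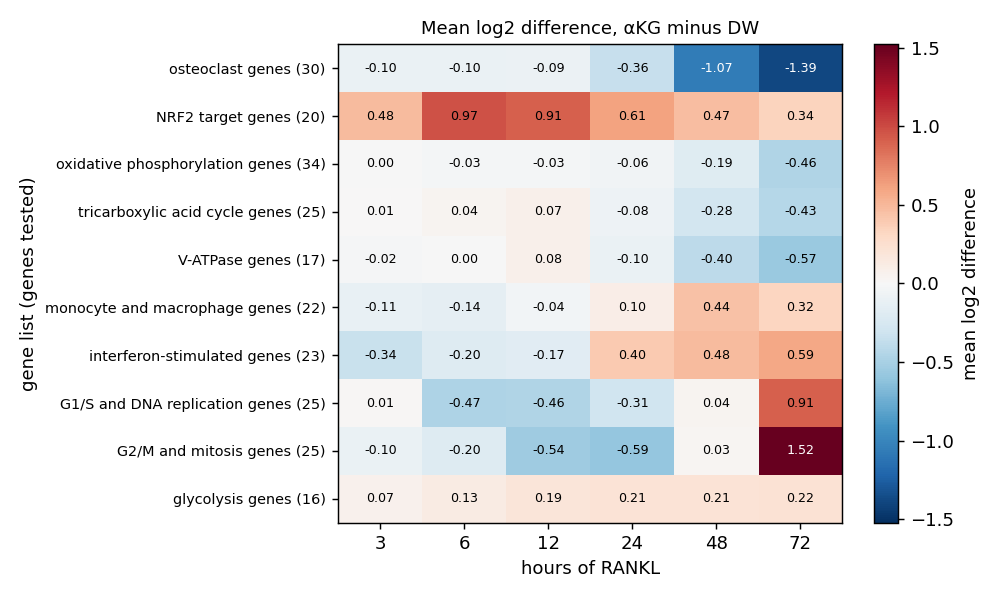
Mean log2 difference (αKG minus DW) of 10 gene lists, in rows with the number of genes tested, at 6 times of RANKL in columns, each from 1 array per arm. Red is higher and blue lower with αKG. Osteoclast genes reached -1.39 at 72 h and NRF2 target genes 0.97 at 6 h.

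Sets defined by RANKL in one phase were then followed in arrays of another phase, so that the fold changes of set and effect came from different arrays. The spread used in both fits was estimated over arrays of all phases, so set and effect are not fully separate. The 70 genes raised in intermediate DW arrays had a mean late αKG effect of -0.10 log2, and the 51 lowered genes one of 0.32, with 40 of 51 above 0. The 519 genes raised in late DW arrays had a mean intermediate αKG effect of -0.08, and the 512 lowered genes one of 0.10. All 4 sets passed camera, and with an estimated correlation the adjusted p = 0.322, 0.156, 0.322 and 0.156 in that order, so none passed; before adjustment the last set had p = 0.0408. The late effect was -0.03 and 0.20 for the first pair of sets without the 48 h arrays and -0.17 and 0.43 without the 72 h arrays. The intermediate effect was -0.14 and 0.14 for the other pair without the 12 h arrays and -0.02 and 0.07 without the 24 h arrays.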

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

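The tests of a single late array, of an equal share of missing osteoclasts and of the delays, and the list means without a pair of arrays, were chosen after the late result had been seen.

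The αKG effect differed between late and early arrays for 94 genes (limma, test of the difference itself, 54 higher and 40 lower). Differences are late minus early log2 effects. Oscar stood at -3.021, Myo1d at -2.699, Steap4 at -2.237, Dcstamp at -2.101, Itgb3 at -2.039, Ext1 at -1.949, Ocstamp at -1.948, Slc9b2 at -1.895, Mt3 at -1.888 and Ccr1 at -1.886. Rasgrp3 stood at 1.605, Platr25 at 1.546, Ceacam1 at 1.524, Klra2 at 1.485, Slc6a12 at 1.456, Fgr at 1.443, Clec5a at 1.44, Cx3cr1 at 1.388, Ccl5 at 1.354 and Trim30c at 1.343. Ctsk (-1.11, adjusted p = 0.0925), Acp5 (-1.12, adjusted p = 0.0506) and Slc7a11 (-2.53, adjusted p = 0.0533) did not pass. With eBayes without a trend 17 genes passed, 3 higher and 14 lower. In the fit of 8 groups without the time block 0 passed. With the αKG effect as a line in log2 time 29 passed, of which 19 were among the 94. The count was 1 without the 3 h or the 6 h pair, 1504 without the 48 h pair and 142 without the 72 h pair.

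By list, the mean late minus early effect was -1.126 for osteoclast genes, -0.328 for RANK signalling genes, -0.32 for NRF2 target genes, -0.416 for ATF4 genes, -0.378 for tricarboxylic acid cycle genes, -0.303 for oxidative phosphorylation genes, -0.472 for V-ATPase genes and -0.461 for cell fusion and actin genes. It was 0.7 for G1/S genes, 0.92 for G2/M genes, 0.804 for interferon-stimulated genes, 0.503 for monocyte and macrophage genes, 0.268 for neutrophil genes and 0.128 for lysosome genes. These 14 lists passed camera, and 0 passed with an estimated correlation, where osteoclast genes had adjusted p = 0.317. They are not all separate, since the cell fusion and actin list shares Dcstamp, Ocstamp, Atp6v0d2, Itgb3 and Src with the osteoclast list. Several means rested on 1 pair of arrays. Without the 72 h pair the mean was 0.27 for G1/S genes, 0.17 for G2/M genes, -0.71 for ATF4 genes and -0.17 for oxidative phosphorylation genes. Without the 48 h pair it was 1.13 for G1/S genes, 1.67 for G2/M genes, -0.12 for ATF4 genes, 0.14 for neutrophil genes and 0.08 for lysosome genes. Without the 6 h pair it was -0.07 for NRF2 target genes and 0.46 for G1/S genes, and without the 3 h pair -0.57 for NRF2 target genes. In late αKG arrays 0 G1/S genes passed (limma), against 18 without the 48 h pair and 0 without the 72 h pair.

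Among 5000 features with no single gene name, which the comparisons leave out, 154 passed in late DW arrays against 0 h, 110 higher and 44 lower.

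The mean of osteoclast genes was lower with αKG in late arrays. The DW array at 72 h alone is argued against by a list mean of -1.07 at 48 h. An equal share of osteoclasts missing from every αKG culture would lower alike only genes expressed in osteoclasts alone, with signals not compressed. Over 20 genes raised more than 3 log2 at 48 h in DW, the late differences spread 4.49 times their median standard error. These include Traf1 (-0.05) and Gstt1 (-0.33), which were lower at 72 h than at 48 h in DW arrays. The spread was 3.58 times over the 12 in the osteoclast list. At 72 h alone it was 2.07 times over 5 osteoclast genes picked in the αKG array at 48 h instead. There Car2 stood at -1.98 and the others between -0.99 and -1.40. The genes thus did not fall by a common amount, but expression in other cells or compression of bright signals could give this too, so an equal missing share stays open. A delay of up to 24 h stays open: αKG at 72 h lay more than 0.5 log2 outside the interval of DW at 48 and 72 h in 55.0% of the 20 genes, 11 below and 0 above (17 and 0 with no allowance), but their choice shares the DW array at 48 h with that interval, and of 8 genes picked in the αKG array at 48 h, which favours genes that αKG lowered less, 12.5% lay outside (7 below and 0 above with no allowance). A delay of more than 24 h stays open as well: the interval of 24 to 72 h, added after the narrower one had failed, left 0.0% more than 0.5 log2 outside (1 gene, Jdp2, below with no allowance) but spans nearly the whole induction. Compression of bright signals, a change within osteoclasts and unknown shared cultures may also contribute.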

How the results depend on the processing

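The camera count with a preset correlation over the 6 times and the counts of single lists without given arrays or the time block were chosen after the data had been seen. Leaving out dim genes at other levels, both scalings, robust eBayes and testing every feature kept the 9 gene counts within 1.5 times, except 5 genes for early αKG with the lowest 50% left out. Centring on array medians gave 15 higher and 4 lower genes for early αKG, against 15 and 10. With only the groups compared in the fit, RANKL counts were 775 early, 0 intermediate and 115 late, and 96 in fast αKG arrays. The fold changes are the same in both fits, and only the estimate of the spread differs. The main fit shares 1 spread per gene over all 8 groups, so later arrays enter the errors of early and fast arrays. The smaller fits have 2 residual degrees of freedom. With eBayes without a trend, αKG counts were 32 over the 6 times, 6 early, 5 intermediate, 323 late and 17 for late minus early (3 higher and 14 lower). The fit of 8 groups without the time block gave 20, 0, 1, 7 and 0 in the same order, and 6 arrays against 6 gave 0; time then adds to the spread by construction. A line in log2 time gave 29 for late minus early. The cause was not tested for the other settings.

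With single arrays or pairs left out, counts ranged from 1 to 2 for early RANKL, 4 to 67 intermediate, 251 to 2179 late, 4 to 174 for αKG over the 6 times, 0 to 2 early, 0 to 1 intermediate, 326 to 1882 late and 1 to 1504 for late minus early. An arm left with 1 array is assumed to vary like the others, and the lower residual degrees of freedom limit these fits. The αKG effect ranged from -0.168 to -0.026 for genes raised by RANKL in intermediate arrays, 0.204 to 0.427 for those lowered, -0.136 to -0.018 for those raised in late arrays and 0.068 to 0.135 for those lowered.

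For the 6 times fry called 3 lists and camera 12; the smallest p of the exact test allowed no call after adjustment unless most lists reached it, so its count of 0 says nothing. Camera called 6, 8 and 14 lists for early, intermediate and late RANKL, 4 for fast αKG, 6, 12 and 13 for early, intermediate and late αKG and 14 for late minus early; with an estimated correlation each was 0, and fry gave 2, 1, 8, 0, 0, 1, 6 and 0 in that order. With an estimated correlation, effects of -0.097 (unadjusted p = 0.274), 0.316 (0.0782) and -0.077 (0.322) for the RANKL sets did not pass; the effect of 0.101 on the last set (0.0408) passed only before adjustment over the 4 sets (adjusted p = 0.156). Of the values of named genes under these settings, 2161 kept their call, 516 no longer passed and 18 newly passed. A change of direction was counted only where the value passed in at least 1 of the 2 fits, and 0 were found. Values that passed in neither fit count as kept whatever their sign, so changes of sign among them are not shown.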

Other observations

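The tests of a shared batch and of growth factor signalling at 12 h were chosen after the 12 h arrays had been seen, and the list of ERK target genes was drawn up after their most deviating genes were known.

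Single genes of other lists also changed with αKG in late arrays. Of 12 heat shock genes 3 rose, Hspa1b (1.29 ± 0.15), Hspa1a (0.90 ± 0.19) and Hsph1 (0.82 ± 0.14), against 3 adjusted over the list alone. Of 16 glycolysis genes 3 rose, the lactate exporter Slc16a3 (0.80), Hk3 (0.61) and Pkm (0.36), also 3 adjusted over the list alone; adjusted p = 0.204 with an estimated correlation. Of 21 lysosome genes 4 rose, such as Ctsl (0.63 ± 0.10), and Hexa fell (-0.47 ± 0.07), against 6 and 1 adjusted over the list alone. Among 11 repressors of osteoclast differentiation, the Notch pathway factor Rbpj rose (0.61 ± 0.10) and Rcan1, an inhibitor of calcineurin, fell (-1.33 ± 0.27), 1 and 1 adjusted over the list alone as well. Of 14 neutrophil genes 2 rose, Mmp8 (0.81 ± 0.18) and Camp (0.69 ± 0.14), and of 6 T and NK cell genes Il7r rose (1.06 ± 0.14) while Cd4 (-1.96 ± 0.27) and Lat (-1.07 ± 0.16) fell; the counts adjusted over the list alone were the same. Of 12 stromal, osteoblast and endothelial genes 2 rose, Cdh5 (0.71 ± 0.15) and Acta2 (0.54 ± 0.11), and of 4 erythroid genes 1 fell, Tfrc (-0.91 ± 0.11).

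Mean αKG effects over the 6 times were -0.001 log2 for 25 genes of 2-oxoglutarate-dependent dioxygenases, a family of enzymes that use αKG, with 0 past the threshold in limma. This is the mRNA level of the enzymes, and their activity was not measured. Mean αKG effects were 0.07 for hypoxia genes, -0.06 for cholesterol biosynthesis genes, -0.07 for LXR target genes, 0.16 for NF-κB genes, 0.12 for immediate early genes, 0.01 for alternative activation genes and 0.08 for ribosome biogenesis genes. They were -0.10 for dendritic cell genes, -0.16 for B cell genes, -0.28 for T and NK cell genes, -0.22 for erythroid genes, 0.01 for mast cell genes, 0.01 for stromal genes, 0.03 for unfolded protein response genes and 0.12 for heat shock genes. Most of the mean came from Cd4 (-1.62) among 6 T and NK cell genes and from Tfrc (-0.71) among 4 erythroid genes. The count of genes at least 2-fold apart between the arms was 17 higher and 12 lower at 3 h and 277 higher and 238 lower at 72 h, from 1 array each. Between these times it did not rise steadily: 47 and 46 at 6 h, 36 and 29 at 12 h, 32 and 25 at 24 h and 68 and 68 at 48 h.

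When the 2 arrays of each time were exchanged between the arms in all 32 ways, 1 assignment, the real one, gave as many as 62 genes. The highest other gave 1. A share of 1 in 32 is the smallest this test can give, so it argues against chance assignment within times without excluding it. Any lasting difference between the arms other than αKG would give the same result. Of 100 splits of the 12 arrays not kept within times, 5 gave as many, the real one included, and the highest other gave 340, so chance is not excluded there. With time as a factor only the pairs a split parts enter the effect. The 3 splits with 340 genes parted the 48 and 72 h pairs and the 1 with 115 parted the pairs from 12 to 72 h, all of them αKG from DW as labelled, so they hold the αKG effect at fewer times. Of 6 drawn splits that part all 6 pairs, the highest other gave 0.

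The mean of NRF2 target genes was higher with αKG than with DW at the same times. For Hmox1 this was a smaller fall in intermediate and late arrays, where DW stood at -1.26 and -1.83 against 0 h. Slc7a11 was not below 0 h in early (2.02) or intermediate (0.59) DW arrays, neither value past the threshold. A general stress response is argued against over the 6 times: the highest mean among ATF4, unfolded protein response and heat shock genes was 0.22 of the NRF2 mean (ATF4 genes without shared members 0.14 ± 0.10, NRF2 genes 0.63 ± 0.11). It stays open at 3 h, where these ATF4 genes stood at 0.29 against 0.48, and at 72 h, at 0.29 against 0.34, and heat shock genes had a mean above 0 at 6 of 6 times (0.12, exact p = 0.03125). A few members carrying the list are argued against by a mean of 0.48 without Slc7a11, Nqo1 and Gclm. A candidate explanation is that dimethyl αKG activates NRF2, by αKG or by the ester itself; no array with another ester was analysed here, so these stay open.

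The 12 h arrays of both arms differed from the mean of 6 and 24 h in like ways (r = 0.79 across genes, which are not independent replicates; SD 0.379 in DW and 0.387 in αKG arrays). So did the 24 h arrays (r = 0.731, SD 0.358 and 0.293) and the 48 h arrays (r = 0.621, SD 0.331 and 0.269) from their own neighbours. The 6 h arrays were less alike (r = 0.344, SD 0.186 and 0.231). Deviations at neighbouring times use some of the same arrays, so these values are not independent of each other. At 12 h in DW and αKG arrays, Ccl2 deviated by -3.15 and -4.20, Myc by -2.49 and -3.32, Cxcr4 by 2.13 and 2.19 and ribosome biogenesis genes by -1.02 and -0.98, and a batch shared by these arrays cannot be told apart from time, since each time has 1 array per arm. A rise in neutrophils of the size set beforehand (0.5) was not reached, with a list mean of 0.40 ± 0.07 in DW and 0.42 ± 0.08 in αKG arrays (standard error over 14 genes), S100a8 at 0.43 and 0.46 and S100a9 at 0.31 and 0.31, but the list stood above 0 in both arms, with Mpo at 0.55 and 0.45 and Elane at 0.59 and 0.32, so a smaller rise stays open. Weaker growth factor signalling may contribute: 14 ERK target genes deviated by -0.59 in DW and -0.75 in αKG arrays. The list was picked with the most deviating genes known, so this is a hypothesis. Other lists deviated about as much in DW and αKG arrays: NF-κB and inflammatory genes by -0.57 and -0.77, immediate early genes by -0.55 and -0.73, and G1/S genes by -0.71 and -0.78. The deviation is thus not particular to ERK target genes.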
